A study of Gallus gallus with 24 samples.

How the data were processed

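Messenger RNA of the thymus was sequenced in 24 samples from commercial broiler chickens, 4 libraries in each of 6 groups, with 1 library per sample. The groups combine 3 conditions with 2 times. Birds were mock-challenged, or were challenged with avian pathogenic Escherichia coli O1 and labelled resistant or susceptible, and samples were taken 1 or 5 days after challenge, at an age of 4 weeks per the labels. How birds were assigned to the resistant or susceptible class is not given in the sources used here. The labels do not say in so many words that the samples of a group came from separate birds, so the p-values measure the spread between these samples.

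Per the labels' protocols, RNA was extracted with a magnetic bead kit and had an RNA integrity number above 9 in every sample. Libraries were made with Illumina's TruSeq kit after poly-A selection, and were sequenced on an Illumina HiSeq in 4 lanes. Each lane held 1 library of each group, so lane and group were not confounded, but the lane of a given library is not given in the sources used here. The kit does not mark strand, so reads of overlapping genes on opposite strands were not told apart.

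The deposited values are raw read counts per transcript, one list per library, without normalization. Per the submitters' processing notes, TopHat2 2.0.9, Bowtie2 2.1.0, HTSeq 0.5.4p3, edgeR 3.0.8 and R 2.15.3 were used, with no role stated for each. The genome build and the annotation are not given in the sources used here. Each list holds 17954 Ensembl transcript identifiers and 5 summary rows of the counting tool. The summary rows name no transcript and were kept out of library sizes and tests. As a percentage of all counted rows, reads outside any annotated feature took 22.8 to 29.6%, reads that fitted more than 1 feature took 4.34 to 5.36%, and reads aligned to more than 1 place took 5.90 to 7.40%. The transcripts took the remaining 58.8 to 65.8%. By these summary rows, reads that fitted several features were not assigned to a transcript, so transcripts that share sequence with a close copy, or exons with another transcript of their gene, are uncertain.

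The files do not pair transcript identifiers with gene names. The table of gene names used here paired 0 of the 17954 identifiers with a symbol or a position. For this reason 32 lists of genes (thymocytes, other cell types, immune and stress pathways) that were fixed by symbol before the data were examined could not be tested. The planned check of the birds' sex on sex-linked genes, the use of sex as a covariate and any check on GC content or length could not be run either. Features are called transcripts and are given by identifier.

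Counts were tested with edgeR 4.0.16 in R 4.3.3. Transcripts with too few counts for a group of 4 were removed with edgeR's filterByExpr, which left 13124. Library sizes were scaled with TMM, and a quasi-likelihood model with robust moderation was fitted to all 24 libraries with 1 coefficient per group. 12 contrasts were tested: susceptible or resistant minus mock and susceptible minus resistant on each day, day 5 minus day 1 within each condition, and the 3 differences of these differences between days. P-values were adjusted by Benjamini-Hochberg within each contrast, and transcripts with an adjusted p under 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values, read counts scaled to a common total per library, were computed from the deposited counts with TMM-scaled library sizes.

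Transcripts were named by a rule fixed before the data were examined, used here without its requirement of a gene symbol. Its exclusion of genes on the W sex chromosome could not be applied either, so a named transcript may be sex-linked. Among called transcripts with a mean log2 CPM of at least 1 and no overlap between the 4 libraries of either group, those with the largest positive and negative log2 fold changes were taken. At most 2 of each direction are printed for susceptible minus mock on each day, and for the differences between days all called transcripts are named. Where a named transcript is also given in another comparison, the rule did not choose it there.

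The total of transcript counts ranged from 4248830 to 18809751 per library, with a median of 13075444.5. No pair of libraries was alike within sampling noise: over the 276 pairs, the smallest chi-square per degree of freedom, on transcripts with at least 10 counts in the pair, was 7.82. The model was tested on simulated data made from the real means, dispersions and library sizes for day 5 susceptible minus mock, on 12937 transcripts. It recovered 3 of 50 transcripts changed 1.5-fold, 22 of 50 changed 2-fold, 48 of 50 changed 4-fold and 49 of 50 changed 8-fold, with 5 calls among 12737 unchanged transcripts. The changed transcripts were drawn only from those above a floor on the mean count, so recovery among the least abundant was not simulated. With no transcript changed, day 1 susceptible minus mock gave 0 calls on 12937 simulated transcripts. The simulation drew each transcript independently. It therefore does not show how many false calls arise where real transcripts vary together between libraries.

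Alternatives fixed before the data were examined were RLE size factors, no filter on low counts, the replicate number as a block, a fit of only the groups compared, DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, an added threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Chosen after seeing the data were a fit without the 20 most abundant transcripts, all libraries thinned to the total of the smallest, a fit without robust moderation, and a fit without day 5 susceptible replicate 1 and day 5 mock replicate 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.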

Results

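Thymus messenger RNA was profiled in broiler chickens 1 and 5 days after challenge with avian pathogenic Escherichia coli (APEC) O1, a bacterium that causes respiratory and systemic disease in poultry. The thymus is the organ in which T cells mature. On each day 4 libraries came from mock-challenged birds, 4 from challenged birds labelled resistant and 4 from challenged birds labelled susceptible. Between 14230 and 15634 of the 17954 annotated transcripts had at least 1 count in a library, and 16693 had one in any library. The libraries held 4248830 (day 5 mock replicate 1) to 18809751 (day 1 mock replicate 2) transcript counts. In the other 22 libraries the totals lay between 8284511 and 15925983.

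Day 5 susceptible replicates 2, 3 and 4 lay apart from all other libraries. The first principal component of log2 CPM held 44.7% of the variance, and these 3 libraries had scores of 101.5, 94.4 and 95.4. Day 5 susceptible replicate 1 scored 11.99, inside the range of the 20 libraries of other groups, which ran from -62.2 (day 5 mock replicate 3) to 24.9 (day 1 susceptible replicate 3). The second component held 11.8%. The 10 most abundant transcripts took 17.5% of the counts in day 5 mock replicate 3, where the TMM factor was 0.739, and 5.72 to 12.1% in the other libraries.

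**Figure D1:**
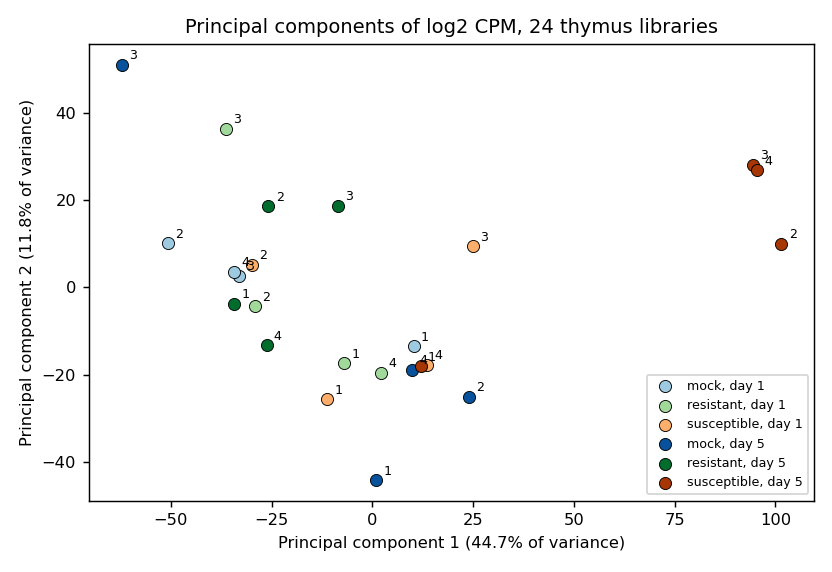
Scores of the 24 libraries on the first (x axis, 44.7% of variance) and second (y axis, 11.8%) principal components of log2 CPM. Each point is a library, coloured by group and marked with its replicate number. Day 5 susceptible replicates 2, 3 and 4 sit at 94.4 to 101.5 on the x axis, and replicate 1 sits at 11.99.

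The comparison of susceptible with mock-challenged birds on day 5 asks how the thymus of challenged birds labelled susceptible differed from that of unchallenged birds. In susceptible birds 2199 of the 13124 tested transcripts were higher and 1860 were lower, together 30.9% of those tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Among called transcripts, rises were larger than falls. How far detection at different abundance shaped this was not tested. The median log2 fold change was 1.38 among transcripts that rose and -0.66 among those that fell, and 1703 rose at least 2-fold against 430 that fell as far. A change of at least 4-fold was found for 308 rising and 25 falling transcripts. The 4 libraries of both groups did not overlap for 14.6% of all tested transcripts, where chance gives 2.86% on average. Transcripts vary together, so the share can lie far from that average by chance, and the gap is not a test.

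The share of transcripts called higher was largest at 1 to 10 CPM, and the share called lower grew with abundance. Of 1095 transcripts with a mean under 1 CPM, 193 (17.6%) rose and 9 (0.822%) fell. Of 3829 transcripts with a mean of 1 to 10 CPM over all libraries, 1185 (30.9%) rose and 109 (2.85%) fell. Of 5882 at 10 to 100 CPM, 727 (12.4%) rose and 956 (16.3%) fell. Of 2318 transcripts over 100 CPM, 94 (4.06%) rose and 786 (33.9%) fell. The transcripts that rose made up 10.3% ± 3.30 (SD, n = 4) of the counts in susceptible birds and 3.97% ± 1.03 (SD, n = 4) in mock-challenged birds on day 5. Those that fell made up 20.2% ± 3.23 (SD, n = 4) and 27.9% ± 0.716 (SD, n = 4). These shares describe transcripts chosen on the same libraries. By library, the risen transcripts held 12.1, 11.9 and 11.8% of the counts in susceptible replicates 2, 3 and 4, and 5.34% in replicate 1.

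ENSGALT00000015790 rose from 1.69 ± 0.966 CPM (SD, n = 4) in mock-challenged to 78.2 ± 54.8 CPM (SD, n = 4) in susceptible birds on day 5. Its log2 fold change was 5.43 ± 0.64 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000233), and the call held under all 19 alternatives. It was higher in 4 of 4 libraries, which the naming rule requires. ENSGALT00000025427 had the largest rise of the rule, with a log2 fold change of 5.72 ± 1.66 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0148). Its level was uneven between susceptible libraries, at 775.3, 25.5, 308.8 and 30.1 CPM in replicates 1 to 4, against 1.94 to 11.1 CPM in the mock libraries. Without susceptible replicate 1 its log2 fold change was 4.48 (adjusted p = 0.0261; range over its 19 alternatives 0.000344 to 0.0442), below the 5.62 of ENSGALT00000015790 in the same fit. ENSGALT00000012958 fell from 5.45 ± 3.06 to 1.10 ± 0.933 CPM (SD, n = 4 each), a log2 fold change of -2.38 ± 0.77 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.024). Under 5 of its 19 alternatives that adjusted p rose above 0.05, up to 0.0786. ENSGALT00000023210 had a log2 fold change of -4.09 ± 0.89 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0038) that rested on day 5 mock replicate 3. That library had 292.7 CPM and the other 3 mock libraries 5.87 to 7.02 CPM, and without it the log2 fold change was -0.47 (adjusted p = 0.21; range over 18 alternatives 0.00265 to 0.21, DESeq2 giving no adjusted p). Over the 10 largest changes of the rule in each direction, log2 fold changes ran from 3.88 to 5.72 and from -4.09 to -1.93.

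The number of transcripts called between susceptible and mock birds on day 5 depended on which libraries entered the fit. A fit of the day 5 susceptible and mock libraries alone called 340 transcripts, 308 higher and 32 lower. The count was 6037 without susceptible replicate 1, 2093, 2331 and 2186 without susceptible replicates 2, 3 and 4, and 2488 without mock replicate 3.

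Susceptible and resistant birds, which received the same bacteria, differed in 5329 transcripts on day 5. Of these, 3045 were higher and 2284 lower in susceptible birds, together 40.6% of those tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). At least 4-fold changes numbered 779 upward and 24 downward. The 4 libraries of both groups did not overlap for 32.7% of tested transcripts, against 2.86% by chance on average, a gap that again is not a test. Of 3829 transcripts at 1 to 10 CPM, 1603 (41.9%) were higher, and of 2318 over 100 CPM, 863 (37.2%) were lower. Both comparisons use the same susceptible libraries. Of their calls, 1917 were higher and 1553 lower in both. Across transcripts the differences had r = 0.92, where unchanged groups that share 1 group gave 0.48 by simulation, and a covariance of 0.615 against 0.0579 simulated. Simulated values are means of 50 runs that drew each transcript independently. They leave out that real transcripts vary together, so the gap from them is not a test. With the susceptible libraries split 2 and 2, so that no library is shared, r averaged 0.78 over 6 splits (0.76 to 0.80). ENSGALT00000015790 was among those higher in both, with a log2 fold change of 4.42 ± 0.59 against resistant birds (SE; edgeR, Benjamini-Hochberg adjusted p = 0.000273), whose level was 3.63 ± 1.88 CPM (SD, n = 4). ENSGALT00000012958 was lower in both (log2 fold change -2.05 ± 0.76 SE; edgeR, Benjamini-Hochberg adjusted p = 0.0369), with 4.43 ± 3.52 CPM (SD, n = 4) in resistant birds. Its libraries overlapped there, with 2.427 CPM in susceptible replicate 1 and 2.323 and 2.025 CPM in resistant replicates 2 and 3. The count of calls was 3522 without susceptible replicate 2, 3255 with libraries thinned to the smallest total and 8604 with limma voom with quality weights. Library measures moved with this comparison: the share of ambiguous reads was 5.22% ± 0.101 in susceptible and 4.87% ± 0.0891 in resistant libraries, and the TMM factor 1.14 ± 0.0900 and 0.966 ± 0.0125 (SD, n = 4 each). Both had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 can give (Benjamini-Hochberg 0.514 over 54 tests). The 10 most abundant transcripts took 7.15% ± 0.485 and 8.98% ± 1.21 of the counts (SD, n = 4 each; exact permutation p = 0.0571).

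Resistant birds had no transcript past the threshold against mock-challenged birds on day 5. edgeR called 0, DESeq2 called 0, and 631 had an unadjusted p under 0.05 where 656 are expected by chance. limma voom with quality weights, which gave day 5 mock replicate 3 a weight of 0.133, called 1505, 746 higher and 759 lower. The transcripts that rose in susceptible birds held 3.79% ± 0.486 (SD, n = 4) of the counts in resistant birds on day 5, close to the 3.97% of mock-challenged birds. Across the 13124 transcripts, which are not independent replicates, the day 5 differences of susceptible and of resistant from mock birds had a Pearson r of -0.11. Unchanged groups simulated against the same mock libraries gave 0.52, and the covariance was -0.0288 against 0.0643 simulated. Transcripts were again drawn independently in the simulation, so the gap is not a test. With the mock libraries split 2 and 2 between the comparisons, r averaged -0.24 over 6 splits (-0.54 to 0.12).

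**Figure D2:**
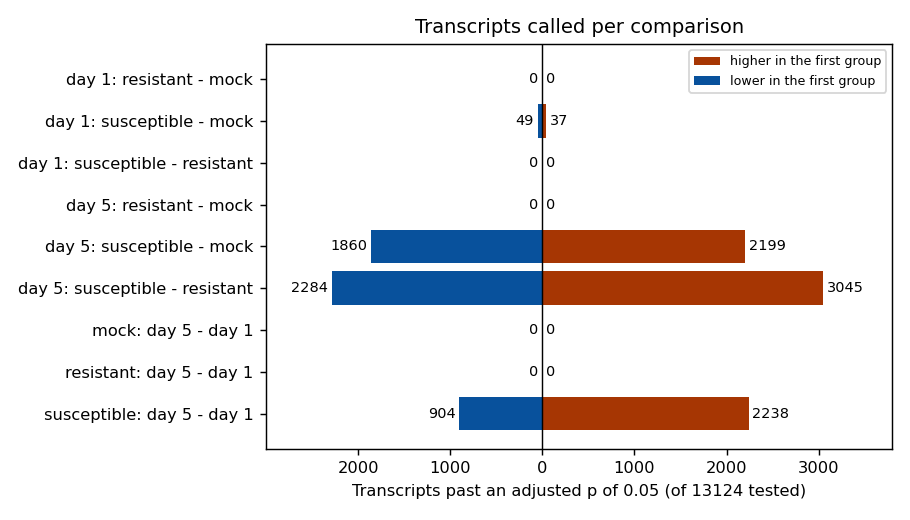
Number of transcripts past an adjusted p of 0.05 (x axis; edgeR quasi-likelihood, 13124 tested) in each comparison of 2 groups (y axis), drawn to the right where the group named first was higher and to the left where it was lower. Of the 9 comparisons drawn, the 3 that include day 5 susceptible birds have 3142 to 5329 calls, day 1 susceptible minus mock has 86 and the other 5 have 0.

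On day 1 the thymus of susceptible birds differed from that of mock-challenged birds in 86 transcripts, 37 higher and 49 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 1.36 among the rising and -0.61 among the falling transcripts. Of the falls, 30 were among the 2318 transcripts over 100 CPM. ENSGALT00000003855 rose by a log2 fold change of 4.74 ± 0.90 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0199), from 6.70 ± 3.68 to 176.5 ± 273 CPM (SD, n = 4 each). Without day 1 susceptible replicate 3, which had 585.8 CPM, its log2 fold change was 2.59 (adjusted p = 0.0831; range over its 19 alternatives 1.46e-05 to 0.0954). ENSGALT00000037229 rose from 2.03 ± 0.292 to 25 ± 33.6 CPM (SD, n = 4 each), a log2 fold change of 3.61 ± 0.72 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0239), which was 2.06 without the same replicate 3 (adjusted p = 0.112; range over its alternatives 1.68e-05 to 0.112). Both were also higher in susceptible birds on day 5, with log2 fold changes of 4.57 ± 0.89 and 4.71 ± 0.75 (SE) and edgeR adjusted p of 0.00224 and 0.000799.

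Among the falling transcripts of day 1, ENSGALT00000044666 dropped from 80.5 ± 4.26 CPM in mock-challenged to 28.8 ± 8.73 CPM in susceptible birds (SD, n = 4 each). Its log2 fold change was -1.48 ± 0.25 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0126), and the call held under all 19 alternatives. On day 5 it stood at 59.1 ± 7.86 CPM in susceptible and 77.9 ± 10.5 CPM in mock-challenged birds (SD, n = 4 each; log2 fold change -0.39 ± 0.25 SE, edgeR adjusted p = 0.218). ENSGALT00000020934 fell from 22.4 ± 8.37 to 5.67 ± 1.10 CPM (SD, n = 4 each), a log2 fold change of -1.98 ± 0.38 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0199). It passed the threshold in 13 of its 19 alternatives (adjusted p up to 0.0986). In resistant birds on day 1 it stood at 7.84 ± 3.86 CPM (SD, n = 4), a log2 fold change of -1.52 ± 0.38 from mock (SE; edgeR, Benjamini-Hochberg adjusted p = 0.488).

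The day 1 count was sensitive to single libraries. It was 91 without mock replicate 1, and 6, 21 and 7 without mock replicates 2, 3 and 4, and it was 10, 49, 17 and 54 without susceptible replicates 1, 2, 3 and 4. The balance of directions moved too, to 32 higher and 17 lower without susceptible replicate 2. A fit of those groups alone called 89 (15 higher and 74 lower), of which 32 were among the 86, DESeq2 called 476 and limma voom with quality weights called 1328. With libraries thinned to the smallest total the count was 22. Without day 5 susceptible replicate 1 and day 5 mock replicate 3, both outside this comparison, it was 1043. At an unadjusted p under 0.05 there were 2054 transcripts where 656 are expected by chance on average. Transcripts vary together, so this gap is not a test. The 10 most abundant transcripts took 7.22% ± 1.21 of the counts in susceptible and 9.49% ± 1.93 in mock libraries on day 1 (SD, n = 4 each; two-sided exact permutation p = 0.0571, Benjamini-Hochberg 0.514 over 54 tests).

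**Figure D3:**
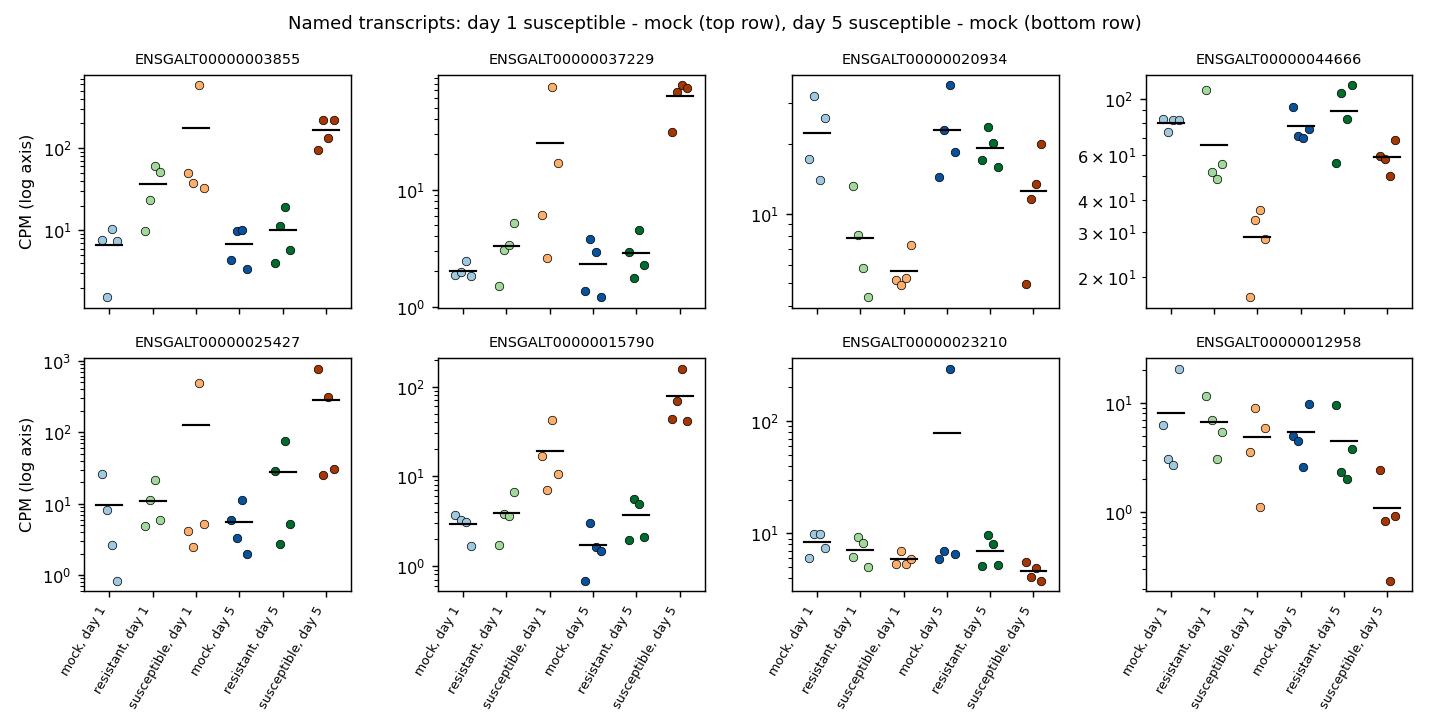
CPM on a log axis (y axis) of the named transcripts in each of the 24 libraries (points), by group (x axis), with the arithmetic group mean as a line. The top row shows those named for day 1 susceptible minus mock and the bottom row those named for day 5. ENSGALT00000015790 lies at 41.8 to 158.2 CPM in the 4 day 5 susceptible libraries and at 0.678 to 3.001 CPM in the 4 day 5 mock libraries.

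Resistant birds did not pass the threshold against mock-challenged birds on day 1 for any transcript. edgeR called 0 with 512 at an unadjusted p under 0.05, DESeq2 called 8 and limma voom with quality weights called 0. Susceptible minus resistant on day 1 gave 0 calls with edgeR, 14 with DESeq2 and 1 with limma voom, with 643 transcripts at an unadjusted p under 0.05. None of the 86 transcripts passed the threshold between susceptible and resistant birds with edgeR, and 36 of the 37 rising and all 49 falling ones had the same sign in resistant minus mock, which shares the mock libraries. Across transcripts, the day 1 differences of susceptible and of resistant from mock birds had r = 0.65, where unchanged groups against the same mock libraries gave 0.5 by simulation. That simulation drew transcripts independently and gives no range for real transcripts that vary together, so the gap is not a test. The covariance was 0.0889 against 0.0601 simulated, and with the mock libraries split 2 and 2, r averaged 0.22 over 6 splits (0.05 to 0.33).

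The changes of susceptible birds on day 1 were compared with those on day 5, which share no library with them. Of the 37 transcripts that rose on day 1, 20 rose on day 5 and 33 had the same sign, and independent lists would share 6.2. Of the 49 that fell, 42 fell on day 5 and all 49 had the same sign, where 6.94 would be shared. These expected numbers take transcripts as independent, which they are not. Both lists also share 1 estimate of spread per transcript from all 24 libraries, so the expected numbers do not measure what unrelated changes would share. ENSGALT00000015790 rose on both days, with a log2 fold change of 2.72 ± 0.57 on day 1 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0317). Over all 13124 transcripts r between the days was 0.49 and rho was 0.48. An exact test over the 70 labellings of the 8 day 1 libraries gave a one-sided p of 0.143 (Benjamini-Hochberg 0.357 over 5 relations; smallest possible p 0.0143), so the agreement over all transcripts was not beyond what relabelled libraries gave.

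Between days, susceptible birds had 2238 transcripts higher and 904 lower on day 5 than on day 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of these rises, 1579 were also higher in susceptible than in mock birds on day 5, which shares the day 5 susceptible libraries. The r between these differences was 0.86, where unchanged groups sharing libraries in this way gave 0.48 by simulation of independent transcripts (covariance 0.478 against 0.0577). In all 3 comparisons of day 5 susceptible birds with 1 other group, 1486 transcripts were higher and 403 lower. A fit of the susceptible libraries alone called 1146. The count was 5631 without day 5 susceptible replicate 1 (3196 higher and 2435 lower), and 1507, 1517 and 1411 without day 5 replicates 2, 3 and 4 (1273, 1269 and 1167 higher, 234, 248 and 244 lower). The balance of directions therefore depended on single libraries, and limma voom with quality weights called 3747 higher and 3454 lower. It was 1496 and 1556 without day 1 susceptible replicates 1 and 2.

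Mock-challenged birds had 0 calls between days with edgeR and DESeq2, 506 at an unadjusted p under 0.05, and 2175 with limma voom. Resistant birds had 0 with edgeR, DESeq2 and limma voom and 398 at an unadjusted p under 0.05. The change between days in susceptible minus mock, which asks whether the response grew, gave 0 calls with edgeR at a smallest adjusted p of 0.125, with 2010 at an unadjusted p under 0.05, 147 with DESeq2 and 2733 with limma voom. Without day 5 susceptible replicate 1 edgeR called 1545, and without day 1 susceptible replicate 3 it called 78. The change between days in resistant minus mock gave 0 calls with edgeR and DESeq2, 904 with limma voom, and 459 at an unadjusted p under 0.05.

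The change between days in susceptible minus resistant passed the threshold for 2 transcripts. ENSGALT00000039793 stood at 2.08 ± 0.474 CPM in susceptible and 2.18 ± 0.489 CPM in resistant birds on day 1, and at 12.4 ± 4.58 and 1.33 ± 0.418 CPM on day 5 (SD, n = 4 each). Its difference of log2 fold changes was 3.27 ± 0.48 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00891), and it missed the threshold under 2 of 27 alternatives (adjusted p up to 0.173). ENSGALT00000012805 stood at 2.59 ± 0.655 and 5.03 ± 0.405 CPM on day 1 and at 8.89 ± 2.62 and 3.34 ± 0.778 CPM on day 5 (SD, n = 4 each), a difference of 2.37 ± 0.39 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0295), which missed the threshold under 12 of 27 alternatives (adjusted p up to 0.12). In total 3090 transcripts had an unadjusted p under 0.05. DESeq2 called 977, limma voom with quality weights 4970, edgeR with RLE size factors 110 and edgeR without robust moderation 104. The count was 2917 without day 5 susceptible replicate 1, 668 without day 1 susceptible replicate 3, 30 without day 5 resistant replicate 3, 19 and 5 without day 1 resistant replicates 3 and 1, 1 or 2 without any other single library, and 0 in a fit of those 4 groups alone.

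The transcripts called between susceptible and resistant birds on day 5 were also read in each library as the mean log2 CPM of those higher minus the mean of those lower. Day 5 susceptible replicates 2, 3 and 4 stood at -1.28, -1.43 and -1.39, and replicate 1 at -3.14. The 4 day 5 resistant libraries lay between -4.23 and -3.74, and the 16 libraries outside that comparison between -4.60 and -2.93. The transcripts were chosen on the day 5 susceptible and resistant libraries, so the distance between those groups follows in part from the choice.

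**Figure D4:**
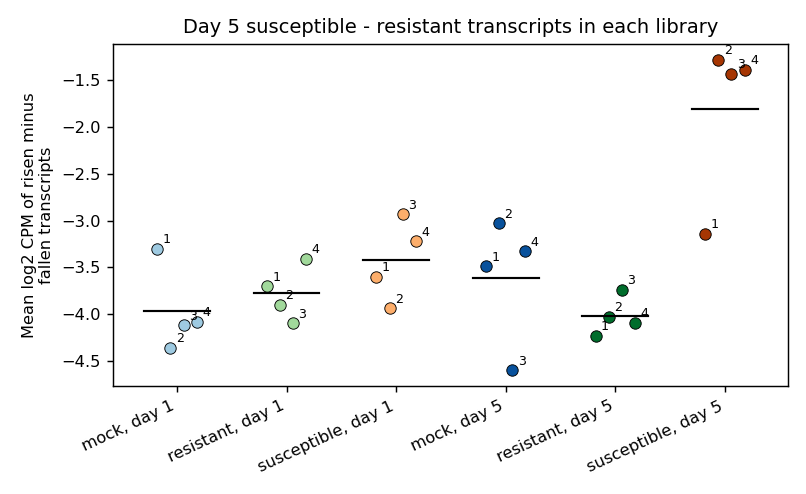
Mean log2 CPM of transcripts higher minus that of transcripts lower in susceptible than resistant birds on day 5 (y axis), in each library (points with replicate numbers) by group (x axis), with the group mean as a line. Day 5 susceptible replicates 2, 3 and 4 sit at -1.43 to -1.28, above all other libraries, and replicate 1 sits at -3.14. The transcripts were chosen on the day 5 susceptible and resistant libraries.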

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

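The tests of an exchanged label, of a weaker copy and of a partial response in day 5 susceptible replicate 1, and both tests of the split of the mock libraries, were chosen only after the result was seen.

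Day 5 susceptible replicate 1 stood apart from the other 3 libraries of its group on the first principal component (11.99), in the number of detected transcripts (15074), in its total of transcript counts (9795539) and in a score made from the transcripts called between susceptible and resistant birds on day 5 (-3.14, against -1.43 to -1.28). An exchange with another library of the series needs a partner that carries the response. Shifts were read on 5956 transcripts (those of the 6037 called without replicate 1 that were also tested with all libraries). On this scale 1 is the mean of susceptible replicates 2, 3 and 4 and 0 that of the day 5 mock libraries. Among the 20 libraries of other groups the highest shift was 0.324 (day 1 susceptible replicate 3). On transcripts called without replicate 2, 3 or 4, that library stood at 0.531 to 0.554 and replicate 1 at 0.423 to 0.438. Replicate 1 enters the reference mean there. Exchanging these libraries gave 4283 calls between days in susceptible birds, against 3142 with the labels given, so that exchange is not excluded. Lower depth is argued against, since susceptible replicates 2, 3 and 4 thinned to the depth of replicate 1 kept a shift of at least 0.983. A weaker copy of the whole response stays open (shift of replicate 1 0.158, mock libraries -0.315 to 0.205), and so does a response in part of the transcripts. Replicate 1 lay beyond all 4 day 5 mock libraries in the called direction for 28.2% of the 5956 transcripts. That share was 6.16 to 21.2% in the day 5 resistant libraries (SD 7.2), 21.5% in day 1 mock replicate 1, and 30.1 and 42.4% in day 1 susceptible replicates 4 and 3. Exchangeable libraries would give 20% on transcripts chosen without these mock libraries. The 5956 were chosen with them, so 20% is not the expected share here. For the 200 transcripts with the largest change the share of replicate 1 was 45.5%, against 43% in day 5 resistant replicate 3 and 52.5 and 68.5% in day 1 susceptible replicates 4 and 3. A wrong label from outside the series and a difference in the course of infection remain open and untested.

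The transcripts called between susceptible and resistant birds on day 5 also varied together in libraries outside that comparison. Over the 16 libraries of the other 4 groups, the score of risen minus fallen transcripts had a within-group SD of 0.49 on the log2 scale, against a median of 0.0945 for 1000 random lists matched on abundance, at percentile 100. Within these 16 libraries the score went with the share of the 10 most abundant transcripts (Pearson r = -0.83, permutation p = 1e-04; Spearman rho = -0.75, permutation p = 0.0012; r = -0.69 without the 2 farthest libraries) and with the share of ambiguous reads (r = 0.81, permutation p = 0.00016; rho = 0.76, permutation p = 0.00097; r = 0.76 without the 2 farthest), with Benjamini-Hochberg values of 0.00032 for both over 4 measures. These correlations used deviations from group means, which the permutations shuffled across all 16 libraries. Deviations within a group are tied to each other, so these p-values are approximate and may be too small. The part of a few abundant transcripts stays open: without the 20 most abundant transcripts the spread was at percentile 100 of random lists, but this takes only 4 transcripts out of the score and left 0.998 of its spread, so it decides nothing, and the correlation with the share of the 10 most abundant goes with it, while depth is argued against, since thinning all libraries to the smallest total left 0.944 of the spread. A varying mixture of cells or dissected tissue between samples was not tested, as no marker gene can be named here, so a biological explanation stays open and untested.

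The 8 mock libraries fell into sets that cross the days. Mock birds gave 0 calls between day 5 and day 1, but setting day 1 replicate 1 with day 5 replicates 1, 2 and 4 against day 5 replicate 3 with day 1 replicates 2, 3 and 4 gave 3814, and no other of the 35 splits gave any, which points to a structure of these samples. An exchange of labels between day 1 replicate 1 and day 5 replicate 3 cannot be told apart from other structure: the relabelled day difference had r = -0.19 across transcripts with the day difference of resistant birds, but those birds were also challenged. The split's fold changes had r = 0.70 with the first axis of within-group variation of 12 challenged libraries (25.6% of their within-group variance), the highest of the 35 splits (next 0.64), so an axis of variation shared with other groups is a candidate explanation that needs no exchanged label. No biological explanation was tested.

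With 4 libraries per group, 120 sets of values were tested for a single library far from the others, and 15 met the rule, where chance gives about 1 in 20. Apart from those above, day 5 mock replicate 1 had the lowest total of its group (4248830 transcript counts). Day 5 mock replicate 3 had the highest share of the 10 most abundant transcripts (17.5%) and the lowest TMM factor (0.739), and day 1 resistant replicate 3 the lowest TMM factor of its group (0.909). On the log2 CPM scale, day 1 susceptible replicate 3 stood at 9.19 for ENSGALT00000003855 and at 8.95 for ENSGALT00000025427, above its group. Day 5 susceptible replicate 1 stood at 4.95 for ENSGALT00000037229 and at 2.52 for ENSGALT00000039793, below its group. Day 1 susceptible replicate 4 stood at 2.90 for ENSGALT00000020934, above its group, and day 1 mock replicate 2 at 6.22 for ENSGALT00000044666, below its group. Day 5 mock replicate 3 stood at 8.19 for ENSGALT00000023210. The difference between susceptible and resistant birds itself differed between the days for 2 transcripts, by the test of that interaction.

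Calls were also counted for other splits of the same libraries. For day 1 susceptible minus mock, 1 of 35 splits gave as many calls, the real one (86, highest other 0). For day 5 susceptible minus resistant it was also 1 of 35 (5329, highest other 3992). That is the smallest count that 35 splits can give and is not adjusted for the 12 comparisons, so it does not exclude chance. A split of the mock libraries that matches no label was likewise the only 1 of 35 with calls (3814). For day 5 susceptible minus mock, 2 of 35 splits gave at least 4059 calls (highest other 5064). For day 5 minus day 1 in susceptible birds 3 of 35 gave at least 3142 (highest other 4283). By rank alone, chance cannot be excluded. The rival splits of the first (5064, 3874, 3515 and 2235 calls) only exchanged day 5 susceptible replicate 1 for a mock library. All its other splits gave 0. Between days, exchanging replicate 1 for a day 1 library gave 4283, 3257, 1610 and 1349, and other splits at most 11. The rival counts thus came from splits that kept the other day 5 susceptible libraries together, not from unrelated groupings. The place of replicate 1 stays undecided by this count. For the change between days in susceptible minus resistant, 9 of 100 drawn splits gave at least 2 calls (highest other 3165), and chance cannot be excluded. A real count of 0 is met by every split, so the count says nothing for the remaining comparisons: it was 35 of 35 for resistant minus mock on day 1 (highest other 1) and day 5 (0), susceptible minus resistant on day 1 (0), and day 5 minus day 1 in resistant (0) and mock birds (3814), and 100 of 100 for the change between days in susceptible minus mock (highest other 2730) and in resistant minus mock (2245).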

How the results depend on the processing

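The fits without the 20 most abundant transcripts, on thinned libraries, without robust moderation and without day 5 susceptible replicate 1 and day 5 mock replicate 3 were chosen after seeing the data. None of the 10 named log2 fold changes turned direction under any alternative run, and DESeq2 gave no adjusted p for ENSGALT00000023210. The gene list tests, their alternatives and sex as a covariate were not run, because no identifier pairs with a symbol or a chromosome here. In what follows, a count is the number of called transcripts, and the cause of a change was not tested except where fewer libraries or a stricter threshold is the change itself.

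RLE size factors moved the change between days in susceptible minus resistant from 2 to 110 calls, no filter to 1, no robust moderation to 104 and thinning to 0. A fit of only the groups compared gave 340 for day 5 susceptible minus mock, 1146 for day 5 minus day 1 in susceptible birds, 1 for day 1 resistant minus mock and 0 for the change between days in susceptible minus resistant. DESeq2 called 476 for day 1 susceptible minus mock, 8 for day 1 resistant minus mock, 14 for day 1 susceptible minus resistant, and 147 and 977 for the change between days in susceptible minus mock and minus resistant. limma voom with quality weights, which gave day 5 mock replicate 3 a weight of 0.133 and day 5 susceptible replicate 1 a weight of 0.168, called 1328 and 1 for day 1 susceptible minus mock and minus resistant, 6873 and 8604 for the same on day 5, 1505 for day 5 resistant minus mock, 2175 and 7201 between days in mock and susceptible birds, and 2733, 904 and 4970 for the changes between days in susceptible minus mock, resistant minus mock and susceptible minus resistant. An absolute log2 fold change of at least 1 left 26 calls for day 1 susceptible minus mock, 2133 and 2916 for day 5 susceptible minus mock and minus resistant, and 2008 between days in susceptible birds. Thinned to the smallest library, these were 22, 2026, 3255 and 1263, which shows how far depth limits the counts.

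Leaving out libraries, the pair chosen after seeing the data included, gave 6 to 1043 calls for day 1 susceptible minus mock, 2093 to 6037 and 3522 to 7589 for day 5 susceptible minus mock and minus resistant, 1411 to 6574 between days in susceptible birds, 0 to 1 for day 1 susceptible minus resistant and for day 5 minus day 1 in resistant birds, and 0 to 1555 and 1 to 4031 for the change between days in susceptible minus mock and minus resistant. The pair gave the 1043, 7589, 6574, 1555 and 4031, and 5071 for day 5 susceptible minus mock.

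Replicate numbers recur in all groups, and whether they mark a shared lane is not given in the sources used here. The data did not settle a pairing. Deviations of same-numbered libraries had correlations of -0.42 to 0.61, 24 of 60 over 0.1 (mean 0.06, against -0.02 for other numbers). Of the 24 libraries, 11 correlated best with their own among the 4 numbers. The mean was higher for same-numbered libraries, so a pairing stays open. With the replicate number as a block the counts were 84 for day 1 susceptible minus mock, 4136 and 5739 for day 5 susceptible minus mock and minus resistant, 3324 between days in susceptible birds, and 2 for the change between days in susceptible minus resistant.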

Other observations

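The test of whether the day 5 response is present on day 1 was written before its result was seen, and the values per library on day 5 were looked at after it.

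The transcripts called between susceptible and resistant birds on day 5 were read in the day 1 groups, which were outside that comparison. All 24 libraries entered the fit, so the day 1 libraries shared in its filter and estimates of spread. The mean of risen minus fallen transcripts, in log2 CPM, was -3.42 ± 0.44 in day 1 susceptible, -3.78 ± 0.29 in day 1 resistant and -3.97 ± 0.46 in day 1 mock birds (SD, n = 4 each). None of these day 1 differences held up: susceptible minus mock was 0.54 (exact permutation test, two-sided p = 0.143, Benjamini-Hochberg 0.486 over 4 tests) and susceptible minus resistant 0.35 (exact p = 0.257). Day 1 susceptible replicate 3 (-2.93) and replicate 4 (-3.22) were the 2 highest libraries of that day, beside day 1 mock replicate 1 (-3.30).

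A hypothesis that the day 5 response of susceptible birds is already present on day 1 could not be settled. Across transcripts r between the days was 0.49, and the exact one-sided p over 70 labellings of the day 1 libraries was 0.143, since other labellings reached 0.66. Leaving out single libraries moved r between 0.33 (without day 1 susceptible replicate 3) and 0.58 (without day 1 mock replicate 1). By library, the deviation from the day 5 mock mean had an r with the day 1 difference of susceptible minus mock of 0.35, 0.50, 0.43 and 0.40 in day 5 susceptible replicates 1 to 4, and of -0.10 to 0.02 in the day 5 resistant libraries.

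Day 5 susceptible replicates 2, 3 and 4 lay beyond all 4 day 5 mock libraries for 96.4, 95.4 and 96.0% of 5956 transcripts (those of the 6037 called without replicate 1 that were also tested with all libraries), a share that describes transcripts chosen on these libraries. On transcripts called without it, replicate 2 had a shift of 1.21, replicate 3 of 1.24 and replicate 4 of 1.22 relative to the mean of the other 3 susceptible libraries. These values exceed 1 because that mean includes replicate 1, which stood at 0.423 to 0.438 on the same scales, below day 1 susceptible replicate 3 at 0.531 to 0.554. The difference from mock computed with 2 of the 4 susceptible libraries and the difference from resistant birds computed with the other 2, which share no library, had a mean r of 0.78 across transcripts over the 6 ordered splits (0.76 to 0.80). Day 1 susceptible replicate 3 lay beyond the mock libraries of day 5 for 42.4% of the same 5956 transcripts, more than any other library outside the group.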
